A study of Homo sapiens with 2 samples.

How the data were processed

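Poly-A RNA of HEK293T cells was sequenced from 2 libraries, 1 transfected with a non-targeting control RNA and 1 with a tRF-3004b mimetic. Per the labels' protocols, each RNA was used at 500 nM, cells were collected after 120 h, and libraries were made with a directional kit after poly-A selection. Per the submitters' processing notes, the authors used kallisto 0.46.1 and the human build GRCh38. Per the file headers, the authors deposited, for each of 70866 RefSeq transcripts, an estimated count, a TPM value (transcript abundance), and the transcript length and effective length in bases. The estimated counts deposited by the authors are not whole, since kallisto shares reads among transcripts that contain the same sequence. TPM values deposited by the authors are scaled over effective length and to a fixed library total, and keep no depth. Gene TPM is the sum over a gene's transcripts, and CPM is the count scaled to the library size. The annotation release, trimming and strand settings are not given in the sources used here.

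Estimated counts were summed per gene and rounded to whole numbers. Transcripts were named with a RefSeq gene table on GRCh38 (70245 transcripts) and with GENCODE release 29 (310 transcripts), and 311 stayed unnamed. The unnamed transcripts held 0.0608% of the control counts and 0.0617% of the tRF-3004b counts, and were left out. Gene coordinates are those of the RefSeq table, 1-based. Of the mitochondrially encoded genes, only the 2 ribosomal RNAs were analysed here. Library sizes were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 (1.02 for the control and 0.983 for the tRF-3004b library). edgeR's test was not used, since 1 library per group leaves no spread to estimate. The log2 ratio is the tRF-3004b library over the control library, with 0.5 counts added at a common library size. Its interval is the exact conditional Clopper-Pearson 95% interval, computed without the added counts. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Where a library had 0 counts, the fold is a lower bound against a floor of 3 counts in that library. Genes entered counts and lists at a mean CPM of at least 1 over both libraries.

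Before the data were examined, 27 gene lists, the seed sites, the alternatives and the rule for named genes were fixed. The rule takes the 15 highest and 15 lowest genes with a mean CPM of at least 10, the 2 highest and 2 lowest measured members of each list, the 5 highest and 5 lowest genes with a site of bases 2 to 8 followed by an A, and AGO1 to AGO4, TRMT6 and TRMT61A. It also gives in full the lists outside the central 95%. That part was kept for the PERK-ATF4, heat shock and tRNA synthetase lists, except for a member that is not reported here, and the longer lists are summarised with examples chosen after their values were seen. Each list's median was given an exact binomial order-statistic interval and a percentile among 10000 random lists of the same size matched on mean CPM in 20 bins. A list was called outside when its median lay beyond percentile 2.5 or 97.5. No p-value is given for a list, since genes are not replicates.

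For seed sites, the 3' UTR was taken from the GENCODE 29 transcript paired with the gene's most abundant RefSeq transcript. This gave 18544 genes, for 17094 of which the most abundant transcript itself was paired. The heptamer complementary to bases 2 to 8 was searched in it. Random lists were matched on mean CPM and 3' UTR length in 10 by 10 bins. They were drawn from all searched genes, site genes included, which draws the difference toward 0. Medians were also ranked among all heptamers found in at least 100 genes. Genes sharing 31-base sequences, the word length used here for what kallisto could not tell apart, were found by search in GENCODE transcripts, and counts were summed over such families.

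The computations were tested on simulated counts for this comparison, drawn from the real means and sizes of 13750 genes with 200 genes changed. The interval lay away from 0 on the correct side for 92% of genes with a log2 change of 2, for 72% with a change of 1, for 82% with a change of -1 and for 80% with a change of -2. Of unchanged genes, 96.3% had an interval that held 0. Of 104 lists drawn without change, 4 lay outside the central 95%. A shift of -0.1 of all genes with the tRF-3004b site, simulated over 12073 genes, gave a difference of -0.07 at percentile 0.00. These simulations hold counting error only. The alternatives were total counts, DESeq2 1.42.0 size factors, a mean CPM of at least 5, no filter beyond 1 count, gene TPM with 1 added, a pseudocount of 5, random lists matched on transcript length, and for seed sites the longest 3' UTR, coding sequences, matching on expression alone, bases 2 to 7 and sites followed by an A. Thinning of the control library to the tRF-3004b depth and removal of the length and GC trend were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.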

Results

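The series asked how the poly-A transcriptome of HEK293T cells, a human embryonic kidney cell line, differed after transfection of tRF-3004b. A tRF is a small RNA derived from a transfer RNA. The mimetic had the sequence TCAAATCTCGGTGGAACCTCCA (22 bases, written as DNA) and the control was a non-targeting RNA of the sequence CGTACGCGGAATACTTCGATT (21 bases). Each was transfected at 500 nM and cells were collected after 120 h. There was 1 library per group, so the comparison has no replicate check and no p-value for a difference between the conditions. It compares these 2 libraries, not the conditions, and each 95% interval of a gene covers counting error only. The control library held 19609933 estimated counts and the tRF-3004b library held 1809193, a 10.8-fold difference in depth. The median gene with a mean CPM (count scaled to library size) of at least 1 had 433 counts in the control library and 34 in the tRF-3004b library.

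In the tRF-3004b library, genes of the ATF4 amino acid and stress response were lower, while chaperones of the heat shock response and ribosome biogenesis factors were higher. CTH, which makes cysteine from cystathionine (chromosome 1, 70411268 to 70439851, GRCh38), was 7.03-fold lower, with 131 CPM in the control library and 18.6 CPM in the tRF-3004b library. HSPA1B, an inducible HSP70 chaperone gene, had a log2 ratio of 2.25 (interval 2.16 to 2.35). Of 13750 genes with a mean CPM of at least 1, 1677 were at least 2-fold higher and 1948 at least 2-fold lower. The whole interval lay beyond 2-fold for 615 higher and 268 lower genes. Counting error alone gave on average 223 higher and 670 lower genes in 100 simulated draws. The draws kept the genes that passed each filter in the real counts and did not filter again. A gene near the filter can pass on high tRF-3004b counts, so 223 may be too low and 670 too high. Among the 8712 genes with a mean CPM of at least 10, 532 were at least 2-fold higher and 745 lower, against 0.39 and 9.37 from counting error alone. Of the genes past 2-fold, 46.3% were higher with TMM-scaled counts and 21.8% with gene TPM and 1 added.

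Among genes with a mean CPM of at least 10, SLC2A12, a sugar transporter (chromosome 6, 133987581 to 134052624), was 11.3-fold lower, with a log2 ratio of -3.50 (interval -5.16 to -2.31). PRSS12, a secreted serine protease (chromosome 4, 118280038 to 118353003), had a log2 ratio of -3.41 (interval -5.08 to -2.22). SLC1A4, a neutral amino acid transporter (chromosome 2, 64988479 to 65023865), had a log2 ratio of -3.11 (interval -5.04 to -1.79). AJUBA followed at -2.84, CYP2R1, a vitamin D hydroxylase, at -2.78, the lipoprotein receptor VLDLR at -2.75, HAUS4 at -2.67, the receptor LRP1 at -2.63 and CARF at -2.61. All these genes had few counts in the tRF-3004b library. SLC2A12 and PRSS12 had 5, SLC1A4 had 4, AJUBA, LRP1 and CARF had 7, CYP2R1 and VLDLR had 6, and HAUS4 had 13. Their intervals were wide and overlapped, as from -4.27 to -1.68 for CYP2R1, so their order is uncertain. AJUBA (chromosome 14, 22971177 to 22982551) and HAUS4 (chromosome 14, 22946228 to 22957090) lie close together. CTH, given above, is also among the 15 lowest. The other 5 of the 15 share sequence with other genes, so their own values are uncertain. LOC102724560 had 3527 counts in the control library and 0 in the tRF-3004b library, at least 105-fold lower against a floor of 3 counts (the interval ended at a log2 ratio of -6.41), but the sum over it and the gene that shares its sequence had a log2 ratio of -0.85. The corresponding sums were -0.39 for SMG1P3, -0.02 for ZNF117 and -0.27 for PMF1-BGLAP. GOLGA8K and its 8 near copies together stayed low, at -2.30.

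Several of the highest genes had few counts. JCHAIN, the joining chain of secreted antibodies (chromosome 4, 70655541 to 70666508), was 26.4-fold higher, with 15 counts in the control library and 39 in the tRF-3004b library. HPGD, which inactivates prostaglandins (chromosome 4, 174490175 to 174522893), was 20.6-fold higher, with 100 and 186 counts. The short RNA BCYRN1 had a log2 ratio of 4.17, the matrix proteoglycan LUM of 3.83, the collagen COL3A1 of 3.19 and the surface protein CD24 of 3.05. LUM and COL3A1 belong to the fibroblast marker list, whose summed counts had a log2 ratio of 1.64. ZNF480 followed at 2.49 and ANKRD12 at 2.39. High entries also included nuclear ribosomal RNA. RNA28SN1 had 114 CPM in the control library and 734 CPM in the tRF-3004b library, and RNA45SN1 had 0 and 83 counts. The libraries were poly-A selected, so these counts need not follow the ribosomal RNA level in the cells. Of the mitochondrial ribosomal RNAs, MT-RNR1 had a log2 ratio of 0.93 and MT-RNR2 of -0.30. The RNA28SN1 locus lies within RNA45SN1 (chromosome 21, 8433222 to 8446572), so the reads of these 2 entries cannot be separated. LOC100507412 had a log2 ratio of 2.56 and GTF2H2C of 2.69, and neither they nor the rRNA genes were searched for shared sequence. For UTP14C, RPL13AP5 and HSPE1-MOB4, which share sequence with other genes, the family sums had log2 ratios of -0.34, 0.00 and 0.88.

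Of the 27 gene lists, 13 had a median outside the central 95% of 10000 random lists matched on expression. The PERK-ATF4 list, which holds targets of the transcription factor ATF4, had the lowest median of the lists. All 28 members were measured, and 23 were lower in the tRF-3004b library, 16 of them at least 2-fold. The median log2 ratio was -1.17 (interval -1.91 to -0.83), at percentile 0.00 of the random lists, whose central 95% ran from -0.37 to 0.25. The intervals of 22 members lay below 0. Log2 ratios were -2.81 for CTH, -2.41 for PCK2, -2.28 for the cystine transporter SLC7A11, -1.91 for asparagine synthetase ASNS and -1.07 for PSAT1, a serine synthesis enzyme. The folate enzymes ALDH1L2 and MTHFD2 stood at -2.06 and -1.39. Among stress regulators, CEBPB was at -2.47, DDIT4 at -2.11, TRIB3 at -1.86, DDIT3 at -1.81, CEBPG at -1.58 and ATF3 at -1.05. In the tRF-3004b library CEBPB, TRIB3, DDIT3 and PCK2 had only 5, 7, 8 and 11 counts, and ASNS had 383. The interval of CEBPB, from -4.14 to -1.27, held the value of ASNS. ATF4 itself was at -0.55 (interval -0.69 to -0.41). CHAC1, a glutathione-degrading enzyme (chromosome 15, 40953471 to 40956512), had 51 counts in the control library and 0 in the tRF-3004b library, at least 1.51-fold lower against a floor of 3 counts, with an interval that ended at a log2 ratio of -0.25. With CHAC1 at that bound, the list's median was -1.06. The further lower members were VLDLR at -2.75, STC2 at -1.27, XPOT at -0.90, PHGDH at -0.88, SLC7A1 at -0.87, SESN2 at -0.83, SHMT2 at -0.47 and SLC7A5 at -0.11. Those above 0 were ATF5 at 1.30, NUPR1 at 1.11, PPP1R15A at 0.40, SLC1A5 at 0.26 and SLC3A2 at 0.09, and of these the interval lay above 0 for NUPR1 alone.

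**Figure D1:**
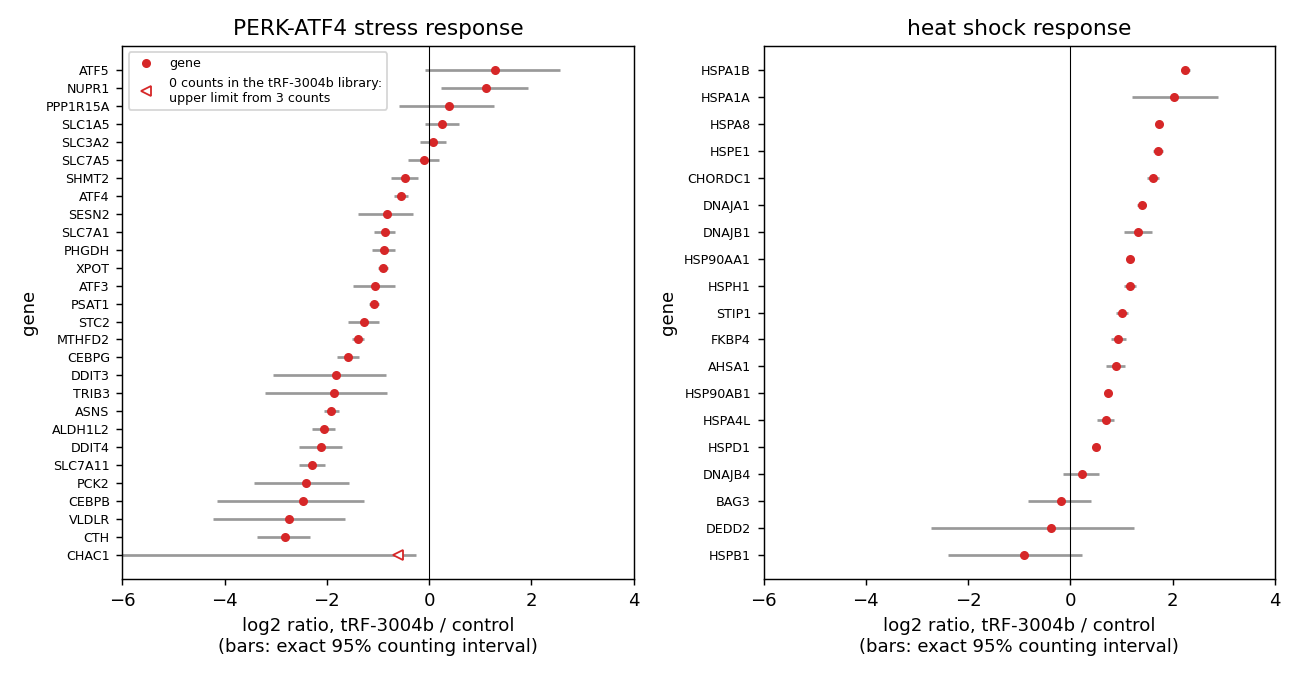
Log2 ratio (tRF-3004b library over control library, x axis) of each measured gene (y axis) of the PERK-ATF4 list (left) and the heat shock list (right); bars are exact 95% counting intervals, and the open triangle is the upper limit for CHAC1, which had 0 counts in the tRF-3004b library. Of the PERK-ATF4 genes 23 of 28 lie below 0, and of the heat shock genes 16 of 19 lie above 0.

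The other branches of the unfolded protein response did not stand apart. The IRE1-XBP1 list had a median log2 ratio of -0.11 (percentile 43.7), from SEC24D at -0.96 and ARFGAP3 at -0.64 to SEC61B at 0.53 and SRP19 at 0.79. The ATF6 list had a median of 0.22 (percentile 90.5), from HERPUD1 at -0.81 and SEL1L at -0.69 to SDF2L1 at 1.09 and MANF at 1.32.

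Heat shock chaperones were higher in the tRF-3004b library. Of 19 measured members 16 were higher, 10 of them at least 2-fold, and none was at least 2-fold lower. The median log2 ratio was 1.01 (interval 0.51 to 1.62), at percentile 100 of random lists. The HSP70 genes HSPA1B, HSPA1A and HSPA8 stood at 2.25, 2.04 and 1.74. HSPA1A and HSPA1B are near-identical copies, so the split between them is uncertain. The mitochondrial chaperonins HSPE1 and HSPD1 were at 1.72 and 0.51, and the HSP90 genes HSP90AA1 and HSP90AB1 at 1.17 and 0.74. The cochaperones CHORDC1, DNAJA1, DNAJB1, STIP1, FKBP4 and AHSA1 were at 1.62, 1.40, 1.32, 1.01, 0.94 and 0.88. HSPH1 was at 1.17, HSPA4L at 0.69 and DNAJB4 at 0.22. The members below 0 were HSPB1 at -0.91, BAG3 at -0.17 and DEDD2, with 44 and 3 counts, at -0.37 (interval -2.72 to 1.26), each with an interval that included 0.

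Ribosome biogenesis factors were higher as a group. Of 35 measured factors 33 were higher, 11 of them at least 2-fold, and 30 intervals lay above 0. The median log2 ratio was 0.72 (interval 0.53 to 0.93), at percentile 100. High members included NOP16 at 1.76, NOP2 at 1.66 and PPAN at 1.69, or 1.55 summed with a readthrough gene that shares its sequence. The abundant nucleolar proteins NPM1 and NCL stood at 1.23 and 0.49, and the rRNA methyltransferase FBL at 0.91. The lower members were NOB1 at -0.48 and POLR1B at -0.10.

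Genes of the p53 target list were lower as a group, and cytosolic tRNA synthetases went both ways. Activity of p53 was not measured, so the name of the p53 list is only a label. Of 23 measured p53 targets 20 were lower, with a median log2 ratio of -0.61 (interval -0.83 to -0.37) at percentile 0.40. SPATA18 was at -1.80 and ZMAT3 at -1.41, whereas CDKN1A, the p21 cell cycle inhibitor, was at -0.60 with an interval from -1.96 to 0.48, and MDM2 at -0.29 (interval -0.44 to -0.15). PHLDA3 had 40 and 0 counts, with an interval that reached 0.12, and BBC3, with 79 and 2 counts, had a log2 ratio of -1.74 (interval -4.89 to 0.09). The highest were RPS27L at 1.07 and TIGAR at 0.31. SESN2 belongs to this list and to the PERK-ATF4 list. Of 20 synthetase genes 12 were lower and 8 higher, with a median of -0.45 (interval -0.86 to 0.16) at percentile 0.11. The intervals of 12 lay below 0 and those of 7 above. CARS1 was at -1.31, AARS1 at -1.12, IARS1 at -0.96, SARS1 at -0.88, GARS1 at -0.87, LARS1 at -0.86, EPRS1 at -0.77, WARS1 at -0.69, MARS1 at -0.58, YARS1 at -0.49, NARS1 at -0.41 and QARS1 at -0.33. FARSA and RARS1 were the highest, at 0.97 and 0.86, followed by HARS1 at 0.54, FARSB at 0.45, VARS1 at 0.39, KARS1 at 0.16 and TARS1 at 0.14.

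Genes of tRNA modification and processing had a median log2 ratio of 0.33 (interval -0.23 to 0.74), at percentile 99.4, with 17 of 27 measured members higher. TRMT10C, a subunit of mitochondrial RNase P, was at 1.48 and SSB, the La protein, at 1.28. TRMT6, a subunit of the tRNA m1A58 methyltransferase (chromosome 20, 5937228 to 5950533), was at 1.04 (interval 0.78 to 1.29). Its partner TRMT61A had 17 and 4 counts, and its interval ran from -0.63 to 3.02. The highest members were CTU1, with 7 and 3 counts at 2.03 (interval -0.32 to 4.40), and CTU2 at 1.65. TRMT2A at -1.25 and ADAT2 at -0.78 were the lowest.

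Transcripts of cytosolic ribosomal proteins, the nuclear-encoded respiratory chain and the proteasome were higher in the tRF-3004b library. Of 79 ribosomal protein genes 72 were higher, with a median log2 ratio of 0.57 (interval 0.46 to 0.71), from RPL3 at -0.59 and RPS29 at -0.31 to RPS26 at 1.29 and FAU at 1.69. Of 42 respiratory chain genes 34 were higher, with a median of 0.48 (interval 0.32 to 0.74), from NDUFS1 at -0.73 and SDHA at -0.40 to COX7B at 1.44 and UQCRB at 1.67. All 31 proteasome subunits were above 0, with a median of 0.66 (interval 0.55 to 0.81), from PSMD2 at 0.01 and PSMC2 at 0.30 to PSMB6 at 1.58 and PSMA3 at 1.65. Each list stood at percentile 100 of random lists matched on expression. Against random lists matched on transcript length as well, the percentiles were 18.2, 30.1 and 97.1. Across all genes with a mean CPM of at least 10, the median log2 ratio was 0.65 in the shortest of 10 length bins and -0.47 in the longest, with a Spearman rho of -0.44 across genes, which are not independent replicates. The PERK-ATF4, heat shock and ribosome biogenesis lists kept percentiles of 0.00, 100 and 100 under the same length matching.

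**Figure D2:**
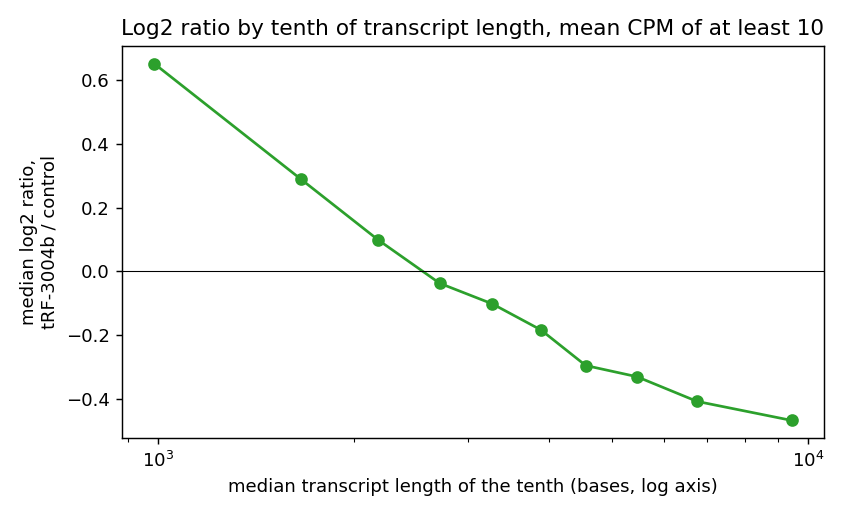
Median log2 ratio (tRF-3004b library over control library, y axis) in 10 equal bins of genes ordered by transcript length (x axis, bases, log scale), for the 8712 genes with a mean CPM of at least 10; points are medians. The median is 0.65 in the bin of the shortest transcripts and -0.47 in that of the longest.

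Interferon-stimulated genes showed no common direction among well-counted members. The median of the 25 measured members was 0.65 (interval -0.09 to 1.64), at percentile 99.6, but among members with a mean CPM of at least 5 it was -0.21 (percentile 41.4). Summed over all 43 genes, the list had 483 CPM in the control library and 460 CPM in the tRF-3004b library, a log2 ratio of -0.07 (interval -0.17 to 0.03). STAT2 was at -0.97, the kinase EIF2AK2 at -0.30 and IFIT5 at 0.42, while DDX60 and HERC6 were the lowest at -1.13 and -0.98. The highest, MX1 and CXCL10, rested on 5 and 8 counts in the tRF-3004b library. MX1, with 1 count in the control library, had an interval from 2.65 to 11.37, and CXCL10, with 3 counts, from 2.85 to 7.45.

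Summed markers of fibroblasts, epithelium and blood were higher in the tRF-3004b library, at low levels. Members such as FBLN1, CDH1 and EPCAM also had counts in the control library (473, 129 and 68), so the lists need not be specific to other cells. Fibroblast markers summed to 39.3 CPM in the control library and 123 CPM in the tRF-3004b library, a log2 ratio of 1.64 (interval 1.42 to 1.86). COL1A2 had 8 and 31 counts, DCN 15 and 34, LUM 34 and 45 and COL3A1 44 and 37, whereas FBLN1, the most abundant member in the control library, had 473 and 37 counts at a log2 ratio of -0.19. PDGFRA was at 0.21. Epithelial and urothelial markers summed to 14.1 and 56.9 CPM, a log2 ratio of 2.01 (interval 1.67 to 2.35), with KRT20 at 4.54 and KRT13 at 4.45 against EPCAM at 0.71 and CDH1 at 0.86. Blood cell markers summed to 4.66 and 34.9 CPM, a log2 ratio of 2.90 (interval 2.42 to 3.38), with HLA-DRA at 4.57, LYZ at 3.65, CD74 at 3.40, PTPRC at 2.78 and LCP1 at 1.76. The medians of the 8, 9 and 5 measured members were 2.11, 2.80 and 3.40, and with gene TPM and 1 added they were 1.25, 1.16 and 2.15.

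**Figure D3:**
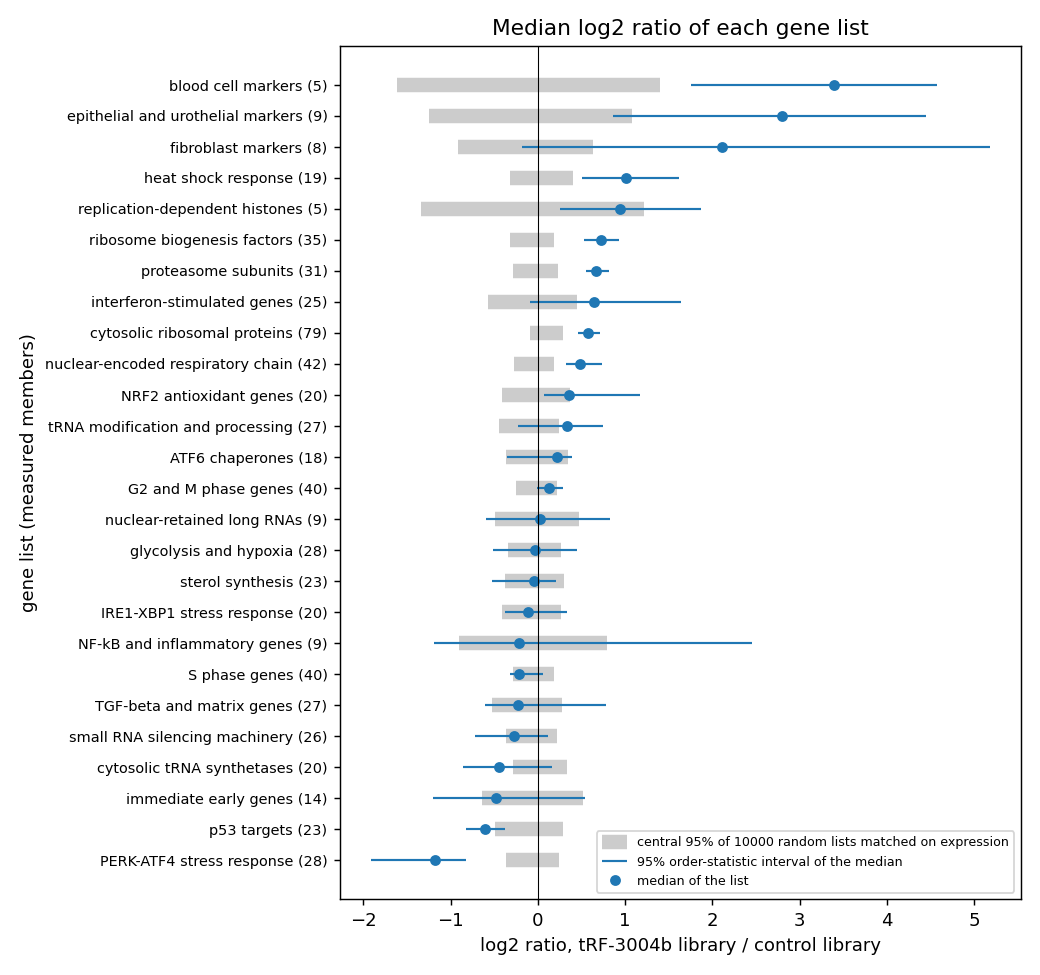
Median log2 ratio (tRF-3004b library over control library, x axis) of each gene list (y axis, measured members in brackets); points are medians, thin lines their 95% order-statistic intervals, and grey bars the central 95% of 10000 random lists matched on expression. The PERK-ATF4 list lies lowest at -1.17, and the heat shock list lies at 1.01.

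The remaining lists with a median lay inside the central 95% of random lists. S phase genes had a median of -0.22 (percentile 9.57), from CDT1 at -1.94 and LIG1 at -1.61 to FEN1 at 0.81 and CCNE2 at 1.04. With random lists matched on length, this list moved to percentile 0.88, but with the length and GC trend removed it stood at 9.9. Genes of G2 and M phase had a median of 0.12 (percentile 89.1), from CDC25C at -1.13 and KIF2C at -0.75 to KIF20B at 1.44 and CENPE at 2.14. NRF2 antioxidant genes had a median of 0.36 (percentile 97.2), from SLC7A11 at -2.28 and TKT at -0.49 to AKR1C2 at 2.81 and AKR1C3, with 3 and 6 counts, at 3.88 (interval 2.26 to 7.12). This list lay outside under 4 alternatives, up to percentile 99.7 with the length and GC trend removed. With random lists matched on length it lay inside, at percentile 81.2. Sterol synthesis genes had a median of -0.04 (percentile 53.6), from LSS at -2.27 and MVD, with 48 and 1 counts, at -1.95 (interval -7.43 to 0.45) to NSDHL at 0.70 and EBP at 0.89. Glycolysis and hypoxia genes had a median of -0.03 (percentile 55.1), from P4HA2 at -1.53 and VEGFA at -1.24 to PKM at 1.01 and EGLN3 at 1.58. Immediate early genes had a median of -0.48 (percentile 7.87), from EGR1 at -1.50 and JUNB, with 30 and 1 counts, at -1.30 (interval -6.77 to 1.17) to CCN2 at 0.59 and DUSP1 at 0.86. The NF-kB list had a median of -0.22 (percentile 34.9), with TNFAIP3 at -1.19, BIRC3 at 2.45 and TNFAIP2 at 2.94, and TRAF1 at 43 and 0 counts, with an interval that reached 0.01. TGF-beta and matrix genes had a median of -0.22 (percentile 33.7), from ITGA5, with 228 and 2 counts, at -3.25 (interval -6.40 to -1.47) and TGFB2 at -1.67 to SPARC at 3.35 and COL1A2 at 5.18. For 5 measured histone genes the median was 0.94 (percentile 94.0), with H2BC5 at 0.25, H2BC21 at 0.34, H1-2 at 1.54 and H2AC6, with 8 and 3 counts, at 1.87 (interval -0.48 to 4.13). Without the filter on low counts the histone median was -0.68. The list labelled nuclear-retained long RNAs had a median of 0.03 (percentile 64.7), from NORAD at -0.80 and TUG1 at -0.60 to KCNQ1OT1 at 0.82 and SNHG8 at 0.91. Where these RNAs lie in the cell was not measured, so the name is only a label. Of the mitochondrially encoded list, MT-RNR1 was at 0.93 and MT-RNR2 at -0.30, with no list median, and the other genes were not analysed here. SDHA, AKR1C2 and TGFB2 share sequence with other genes, and their family sums were at -0.36, 2.88 and -1.47.

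The small RNA silencing machinery had a median log2 ratio of -0.27 (percentile 10.5). Against random lists matched on length as well the percentile was 59.5, and with the length and GC trend removed the median was 0.0026 (percentile 69.3). AGO2, the Argonaute with slicer activity (chromosome 8, 140520156 to 140642313), was at -0.40 (interval -0.60 to -0.20), and AGO4 (chromosome 1, 35807636 to 35857890) was at -1.28 (interval -1.77 to -0.82). AGO1 was at 0.35 (interval 0.05 to 0.63) and AGO3 at -0.28 (interval -0.60 to 0.03). TNRC6C and MOV10 were the lowest members, at -1.98 and -1.56, and TARBP2 and RAN the highest, at 1.28 and 0.64.

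Genes with a seed site for tRF-3004b in the 3' UTR did not stand apart from matched genes. Some tRFs act through Argonaute like a miRNA, whose seed pairs with the 3' UTR, so the heptamer AGATTTG, complementary to bases 2 to 8 of the mimetic, was searched. It occurred in 1827 of 12208 genes, whose median log2 ratio was -0.25 (interval -0.28 to -0.21). Random lists matched on expression and 3' UTR length had a median of -0.23, a difference of -0.02, and the site genes stood at percentile 15.8. The 579 genes whose site is followed by an A had a difference of -0.03 (percentile 13.8), the 1516 genes with bases 2 to 7 followed by an A were at percentile 16.8, and the 4140 genes with bases 2 to 7 at percentile 67.4. AGATTTG ranked 7998 from the lowest of 15658 heptamers by median log2 ratio. Among the genes with the site followed by an A, the lowest were ROR1 at -2.33, COL4A6 at -2.24, PABIR3 at -2.03, SESTD1 at -1.96 and PFKFB2 at -1.79. The highest were WTIP at 1.73, UQCRB at 1.67, RGS5 at 1.58, COPS2 at 1.39 and ALG14 at 1.19. In coding sequences, 1575 genes with AGATTTG had a median of -0.29, a difference of -0.05 from lists matched on expression and coding length (percentile 0.07). These lists were not matched on the length of the whole transcript.

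**Figure D4:**
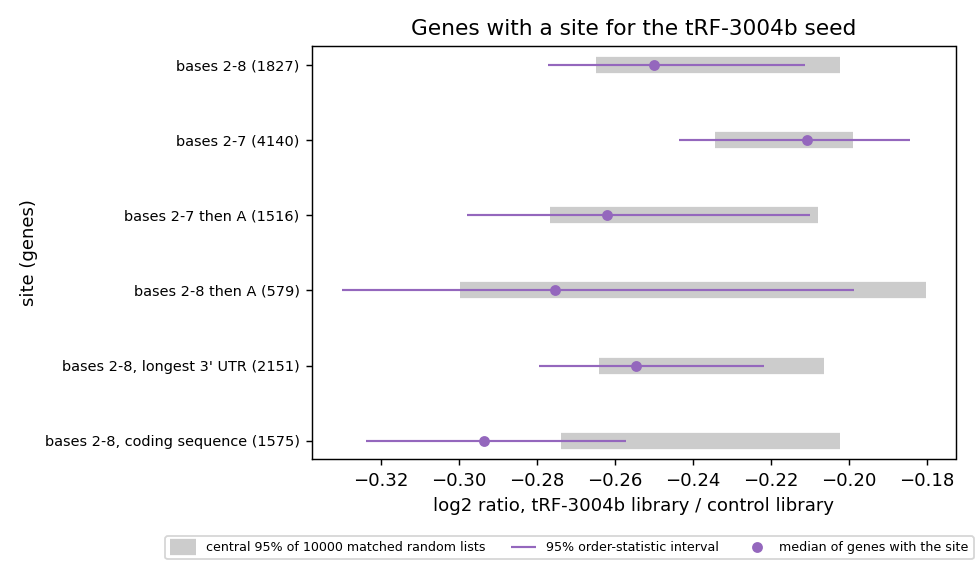
Median log2 ratio (tRF-3004b library over control library, x axis) of genes with each kind of site for the tRF-3004b seed (y axis, number of genes in brackets); points are medians, thin lines 95% order-statistic intervals, and grey bars the central 95% of 10000 random lists matched on expression and on the length of the searched region. The 1827 genes with the heptamer in the 3' UTR lie at -0.25, inside the grey bar, and the 1575 genes with it in the coding sequence lie at -0.29, below it.

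For the control RNA, 28 genes carried the heptamer CGCGTAC in the 3' UTR. Their median log2 ratio was -0.07 (interval -0.48 to 0.12), 0.19 above matched random lists (percentile 85.5), inside the random range of -0.58 to 0.10. The 284 genes with bases 2 to 7 of its seed had a median of -0.38, a difference of -0.11 (percentile 0.91). Silencing by the control RNA would lower these genes in the control library and raise the ratio, so this difference runs the other way.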

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

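There was 1 library per group, so no library could be left out. No paired analysis was possible because each group has a single library. The control thinned to the tRF-3004b depth and the removal of the length and GC trend were chosen after seeing the data. The PERK-ATF4, heat shock, ribosome biogenesis, p53, tRNA synthetase, tRNA modification and fibroblast lists stayed outside the central 95%, on the same side, under all 9 alternatives. The PERK-ATF4 median ranged from -1.49 to -1.08. Gene TPM moved the median of all genes by -0.28, and values under it are relative to that shift; the p53 median became -0.92, ribosomal proteins 0.23, ribosome biogenesis 0.38, respiratory chain 0.16 and proteasome 0.35. With TPM 679 genes were at least 2-fold higher, and TIGAR stood at -0.023, a move of about the shift of all genes. With a mean CPM of at least 5 there were 708 higher and 1077 lower genes, since fewer genes enter. With no filter there were 3081 and 5164, since more genes with few counts enter. The stricter filter of 5 CPM turned the interferon-stimulated median to -0.21 (percentile 41.4), and with TPM that list was at 0.08 (percentile 97.3), inside the central 95%. The fibroblast median was 3.51 with the stricter filter, 1.34 with the thinned control, 1.25 with TPM and 3.44 with the trend removed; the epithelial median was 1.16 with TPM and 1.503 with a pseudocount of 5, and the blood median 2.15 and 2.17. The stricter filter left fewer than 3 epithelial and blood markers, so those lists have no value under it. Removing the length and GC trend turned ribosomal proteins to -0.0087, the respiratory chain to -0.087, PSMC2 to -0.093 and SEC61B to -0.15, and moved the proteasome to 0.20. The proteasome list still lay outside under it, at percentile 98.2, and was inside only with matching on transcript length. The NRF2 list went outside with no filter (percentile 97.7), a pseudocount of 5 (97.6), the thinned control (99.0) and the trend removed (99.7). Matching on transcript length put it at 81.2. The histone median was -0.68 with no filter, 0.05 with the thinned control and 0.13 with the trend removed, and with TPM its percentile was 98.5. For the tRF-3004b seed the difference was -0.054 in coding sequences and -0.15 with matching on expression alone, which leaves the length trend in. For the control seed it was -0.23 with sites followed by an A (11 genes); the cause was not tested. The depth of the tRF-3004b library limits genes of low expression.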

Other observations

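Gene families defined by the letters of their symbols, chosen after seeing the data, gave groups that overlap the fixed lists only in part. Of 93 families with at least 15 measured genes, 14 lay outside the central 95% of random lists matched on expression and transcript length, where chance gives about 4.65. Higher than their random lists were the mitochondrial ribosomal proteins, with a median log2 ratio of 0.79 for 51 MRPL genes (interval 0.70 to 0.99, percentile 99.7) and 0.68 for 30 MRPS genes (percentile 99.3). The 16 TIMM genes, which serve protein import into mitochondria, had a median of 0.66 (percentile 98.0), with 15 higher and 1 lower. The 36 DDX and 16 DHX helicases had medians of 0.29 and 0.14, the 38 RBM genes 0.15, the 37 CD genes, among them CD74 of the blood markers, 0.56 and the 15 PSMD genes, part of the proteasome list, 0.70. The 466 ZNF genes had a median of -0.03, above a random range of -0.32 to -0.14. Below their random lists were 52 ANKRD genes at -0.52, 30 TTC genes at -0.44, 248 SLC transporters at -0.31, 157 TMEM genes at -0.20 and 24 SNHG RNAs at -0.04.

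Of the tests below, the thinning of the control library and the markers outside the lists were written before their results were seen; the others were chosen after. The PERK-ATF4 list had a median log2 ratio of -1.17. After removal of the length and GC trend it was -1.08, below the random range of -0.34 to 0.19, which argues against that trend as the whole cause. With the control library thinned to the tRF-3004b depth it was -1.17, below -0.38 to 0.26. Thinning keeps each gene's expected ratio, so it tests only the counting error of the control and cannot decide on other effects of depth. Another difference between the cultures, such as nutrient state or density, cannot be told apart from the transfected RNA with 1 library per group. A lower ATF4 response in tRF-3004b cells therefore stays a hypothesis, which replicate cultures of each group would test.

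The ribosomal protein and respiratory chain lists may follow the length trend. Ribosomal protein genes made up 26.7% of their own matching pool, so members were left out of the random lists. The ribosomal protein list then stood at percentile 5.31 and the respiratory chain list at percentile 29.7, no higher than other genes of the same length and expression. What produced the length trend, for instance RNA integrity or fragment selection, was not tested.

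The higher markers of fibroblasts, epithelium and blood may come from RNA or reads of another tissue in the tRF-3004b library. Of 4 marker lists outside the fixed ones, picked after the pattern was seen but before their own values were, colon epithelium had a pooled log2 ratio of 2.75 and a lower bound of 1.38, above the upper bound of 1.22 for brain (-0.29 to 1.22), while smooth muscle, with 467 and 77 counts, had 0.89 (interval 0.52 to 1.24) and liver 2.07 (interval -0.48 to 4.13). The colon value rests on 15 counts in the control library and 9 in the tRF-3004b library, in 3 of 12 genes, so the margin is small and no source tissue is named. Picked by CPM in the tRF-3004b library, the top members were PIGR for colon (3 and 4 counts) and MYH11 for smooth muscle (18 and 29). For liver and brain they were SERPINA1 (0 and 2) and GFAP (16 and 7). A similar number of stray reads in both libraries would also give higher CPM in the shallower library. It could give the gap between colon and brain too, since expression by the cells draws a pooled ratio toward 0. The brain list had 142 and 18 counts, so this gap does not separate the 2 explanations. Of the 43 markers, 4 had more raw counts in the tRF-3004b library at a one-sided binomial p below 0.05 (COL1A2 with 8 and 31, DCN 15 and 34, KRT20 10 and 24, HLA-DRA 5 and 14). Equal numbers give 0.81 such genes, with a binomial probability of 0.0080 of as many from counting error only. That probability treats genes as independent and reads as separate molecules, but markers of the same cell type can move together. Pooled raw ratios were 0.28 for fibroblast (0.58 without FBLN1), 0.36 for epithelial and 0.67 for blood markers. The test therefore does not exclude equal numbers, and unequal numbers stay open as well. Transcription of these genes by the transfected cells, with a pooled log2 ratio of 2.90 for the blood markers, cannot be told apart from reads of another tissue with these values.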
